A study of Sus scrofa with 9 samples.

How the data were processed

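The series holds 9 libraries of messenger RNA from pig (Sus scrofa) embryonic stem cells in 3 groups of 3. In the first group the cells grew on feeder cells, in the second on coated plates without feeder cells, and in the third on coated plates without feeder cells with LDN-193189, an inhibitor of the type I receptors of bone morphogenetic proteins (BMP), at 250 nM. Per the labels' protocols, all media held FGF2 at 20 ng/mL, activin A at 5 ng/mL, a compound named CH at 1.5 µM and IWR-1, an inhibitor of WNT signalling, at 2.5 µM, and Y-27632 at 10 µM was present around each passage. Feeder-free cells had been cultured for over 3 passages without feeder cells. Per the same protocols, cells grown on feeder cells were sorted for the surface marker SSEA4 on magnetic columns before RNA extraction, to take out feeder cells and differentiated cells, and no sort is given for the other 2 groups, so that the first group may differ from them by the sort as well as by the culture. Poly-A RNA was made into TruSeq libraries and sequenced as paired ends of 100 bp. Fetal fibroblasts named in the design text were not analysed here.

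The deposited table holds 1 value per gene and library in FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments), as the authors computed them. Per the submitters' processing notes, the tools were FastQC, cutadapt 1.6, TopHat2 2.0.12.1 and Cufflinks 2.2.1, with the genome build Sscrofa10.2. The settings, the annotation release and any scaling between samples are not given in the sources used here. The kit named in the labels does not by its name tell whether strand was kept, so reads of overlapping and antisense genes may be shared, and so may reads of near-identical copies. The number of reads per library is unknown, since the table holds no counts, and no counting interval or detection floor could be given. The relative depth of the libraries could be estimated, because ratios between libraries of values below 0.3 FPKM can fall on steps of whole fragments. It was taken from the commonest ratio to with-feeder replicate 1 and tested on simulated data, an estimate added after seeing the data. In 4000 simulated genes the known depths were recovered within 0.03%, with 22.5% to 28.2% of ratios near the step, against 13.1% to 30.0% in the data, so the estimates for libraries with few such ratios are less certain. An exact 0 may be a failed estimate, and such a gene is only said to be listed at 0.

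The table has 25285 rows. Of these, 16274 carry a gene name, and 1841 of the 9011 others were named through a table of gene IDs and symbols, in which 11791 IDs matched. Names that a spreadsheet had turned into dates (25 rows) were replaced from the same table. Rows of small RNA families numbered 2348, no row lay on a mitochondrial chromosome, and 7805 rows were at 0 in all 9 libraries. Coordinates are those of the deposited table, in Sscrofa10.2.

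From these values, log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (linear model with 3 group means over all 9 libraries, trended and robust prior, two-sided), for the 13222 genes with a mean of at least 0.5 FPKM. P-values were adjusted after Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. The labels do not say that the replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical. The design had foreseen a count test in case the table held counts, and the fit to FPKM was fixed with it as the test for a normalized unit.

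Before the data were examined, 32 gene lists with 475 entries were fixed, and 394 entries matched a row. Some genes belong to more than 1 list, so results of such lists are not independent. GATA2 and GATA3 are BMP targets and trophectoderm genes, KRT8 and KRT18 trophectoderm and epithelial junction genes, and TFAP2C a trophectoderm and germ cell gene. The 31 lists with at least 3 tested members were tested with camera (preset correlation 0.01), adjusted over the lists within a comparison, with camera at an estimated correlation and fry beside it. Camera compares a list with all other genes, whereas fry asks whether its genes move, on balance, one way. Fry called most of the tested lists in every comparison, so a call with it sets no list apart. Its results are given only for the BMP target list and for lists set beside it. Genes named in the text follow a rule fixed at the same time. The rule takes the 6 genes with the largest rise and the 6 with the largest fall among genes with a symbol that were called, had a mean of at least 5 FPKM in the higher group and did not overlap between the groups in any library. It adds, for each list described, up to 4 called members with the smallest adjusted p (or the 2 with the highest mean where fewer than 2 were called), and 12 fixed genes. Of the fixed genes, ID3 and TBXT matched no row and CDX2 lay under the filter. A list gene needed for a check may also be named.

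Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, quantile normalization, TMM factors computed on FPKM, limma without trend and robust, only the 6 libraries of the 2 groups, the replicate number as a block, each library left out, a log2 fold change of at least 1, and the estimated correlation in camera. Cyclic loess normalization, leaving out the small RNA rows, and removing a trend on genomic span were added after seeing the data. The last subtracts from each library's deviation from the gene mean its lowess trend (fraction 0.3) on the log2 distance between the gene's start and end. The fit was tested on simulated data with the means and spread of the 12953 simulated genes that passed the filter and 200 genes changed by a known fold in the comparison without against with feeder cells. It recovered 98.4% of genes changed 4-fold, 90.5% of those changed 2-fold and 45.5% of those changed 1.5-fold, with 9 false calls among 157. The simulated noise was independent between libraries, had the same spread in every group and held no gradient. Far fewer genes changed than were called in the data, so these shares need not hold for the data. Overlaps between comparisons that share libraries were set beside 50 simulations of unchanged groups. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.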

Results

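Messenger RNA was measured in embryonic stem cells of the pig that grew on feeder cells, without them, or without them in the presence of the BMP receptor inhibitor LDN-193189 (250 nM), with 3 libraries in each of the 3 groups. Expression is given in FPKM as mean ± SD over n = 3 libraries unless stated otherwise. The deposited values summed to between 699396 and 822054 FPKM per library. The number of reads behind them is unknown, but relative to with-feeder replicate 1 the depth estimated from low values was 0.923 and 1.004 in the other with-feeder libraries. It was 0.961, 0.868 and 0.881 in the untreated feeder-free libraries and 1.003, 1.247 and 1.199 in the LDN-treated ones, each in order of replicate. These are rough estimates, as only 13.1% to 30.0% of the ratios behind them lay within 0.05 log2 of the value chosen. Between 15140 and 15713 genes had a value above 0 in a library, and 13222 genes with a mean of at least 0.5 FPKM were tested.

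The with-feeder libraries lay close together, and the feeder-free libraries were spread along the first principal component, which held 61.2% of the variance. With-feeder libraries scored between -45.25 and -44.45 on it, LDN-treated libraries between -3.73 and 15.4, and untreated feeder-free libraries 19.2, 55.4 and 42.6 in replicates 1, 2 and 3. The same order appeared in genes with a long genomic span, the distance between a gene's start and end. Genes were divided by span into 4 classes of equal size. For counts of genes, the classes were formed over all tested genes. For values at a matched level, they were formed within each of 10 bins of mean level, and the differences were averaged over the bins. Relative to the mean of the 9 libraries and at a matched level, genes in the longest class stood above those in the shortest class by 0.247 to 0.295 (median log2) in with-feeder libraries. They stood at -0.111, -0.426 and -0.319 in untreated feeder-free replicates 1, 2 and 3, and between -0.0732 and 0.0604 in LDN-treated libraries. Within groups, correlations of log2 values across genes were 0.986 to 0.988 with feeder cells, 0.974 to 0.985 without feeder cells and 0.986 to 0.989 with LDN.

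**Figure D1:**
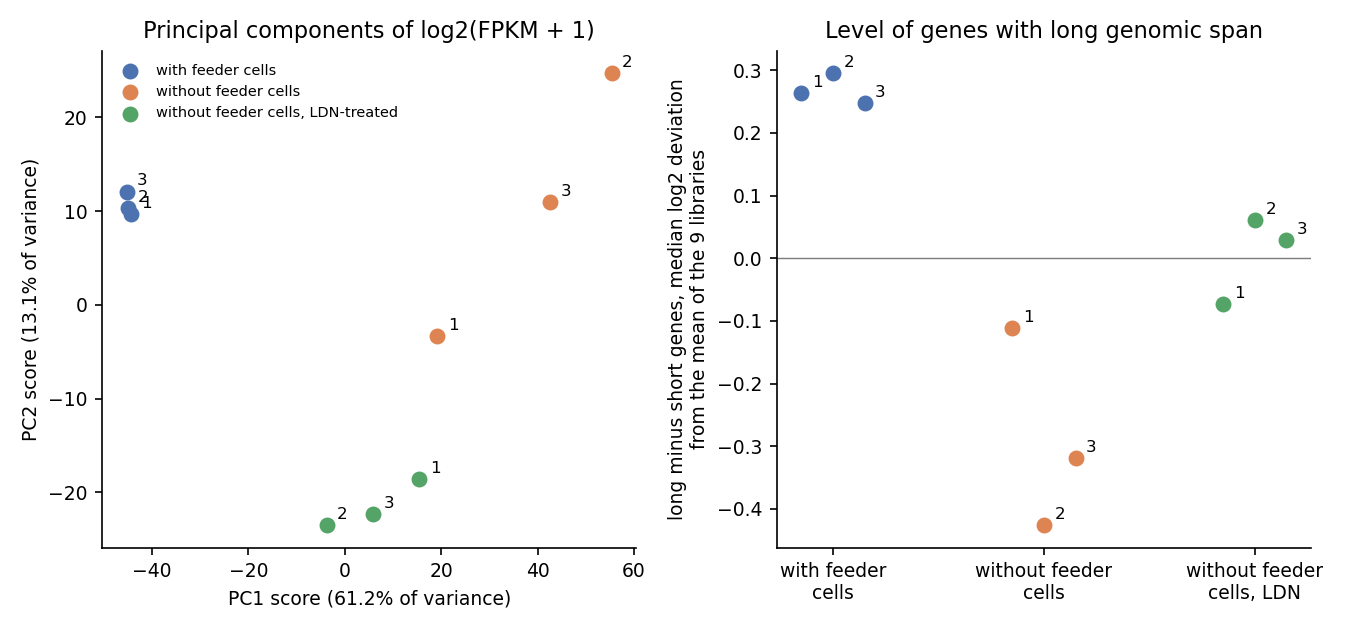
Left, scores of the 9 libraries on the first and second principal components of log2(FPKM + 1), colored by group and numbered by replicate. Right, for each library, the median log2 deviation from the mean of the 9 libraries of genes in the longest of 4 classes of genomic span minus that in the shortest. These classes were formed within each of 10 bins of mean level, and the differences were averaged over the bins. With-feeder libraries lie at 0.247 or above, and untreated feeder-free libraries at -0.111 or below.

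The first comparison asked what changed when the stem cells were moved from feeder cells to coated plates. Per the labels, the cells on feeder cells were sorted for SSEA4 before RNA extraction, and no sort is given for the others. Among the genes that rose most was SFN, which encodes the epithelial protein stratifin, from 16.8 ± 0.858 to 243 ± 43.3 FPKM (log2 fold change 3.76, SE 0.12, limma adjusted p = 2.17e-07). UPK2, a urothelial membrane protein gene, rose from 0.591 ± 0.18 to 33.9 ± 2.95 FPKM. CYP1A1, a detoxification enzyme induced through the aryl hydrocarbon receptor (chromosome 7, 63491454 to 63497651, Sscrofa10.2), rose from 0.206 ± 0.148 to 48.1 ± 1.38 FPKM (log2 fold change 5.35, SE 0.10). The immediate early transcription factor genes EGR1 (chromosome 2, 146156065 to 146160020) and FOS fell. EGR1 went from 142 ± 4.33 to 6.80 ± 0.728 FPKM (log2 fold change -4.20, SE 0.08, limma adjusted p = 9.74e-09) and FOS from 88.1 ± 3.70 to 5.60 ± 0.45 FPKM. Of the pluripotency factors, POU5F1 rose from 1281 ± 53.1 to 2249 ± 349 FPKM, whereas SOX2 fell from 270 ± 19.1 to 180 ± 46.0 FPKM and LIN28A from 1026 ± 21.3 to 489 ± 112 FPKM.

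The other genes with the largest rise were FXYD4, a regulator of the sodium pump, CST6, a protease inhibitor, and PBD-2, a defensin. FXYD4 went from 0.535 ± 0.526 to 75.8 ± 43.9 FPKM and CST6 from 1.03 ± 0.208 to 28.5 ± 3.77 FPKM. PBD-2 was listed at 0 in all 3 with-feeder libraries and at 26.5, 6.47 and 28.4 FPKM in the feeder-free ones. The other genes with the largest fall were PLDN, PRKACG, MTMR12 and a second, short row of ACACA of 225 bp (chromosome 12, 40369503 to 40369727), with log2 fold changes of -3.17 (SE 1.00), -3.01 (SE 0.86), -2.70 (SE 0.43) and -4.51 (SE 1.18). The call of PLDN was lost with a pseudocount of 0.1 or without with-feeder replicate 3, and those of PLDN and PRKACG without feeder-free replicate 2.

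Genes of the trophectoderm, the outer layer of the blastocyst, rose as a group, with 7 of the 8 tested members higher (7 adjusted over the list alone) and none lower (camera adjusted p = 2.55e-05, adjusted p = 0.171 with an estimated correlation). Adjusted over the list alone, 1 member was lower. Keratin 8 (KRT8) went from 1647 ± 47.7 to 4843 ± 397 FPKM, KRT18 from 1040 ± 11.8 to 2955 ± 313 FPKM and KRT19 from 405.5 ± 9.49 to 1295 ± 68.0 FPKM. The transcription factor genes GATA2 and GATA3 went from 0.351 ± 0.138 to 3.81 ± 1.00 FPKM and from 0.125 ± 0.0143 to 3.89 ± 1.30 FPKM, while CDX2 stayed at or below 0.277 FPKM in every library. Surface ectoderm and amnion genes also rose (4 of 5, and 5 adjusted over the list alone, camera adjusted p = 0.003, adjusted p = 0.321 with an estimated correlation), among them DLX3 from 0.112 ± 0.0837 to 8.69 ± 3.53 FPKM and TFAP2A from 0.0537 ± 0.0466 to 3.91 ± 1.82 FPKM. In the list of epithelial junctions, 6 of 12 members rose and 4 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0193 upward, adjusted p = 0.171 with an estimated correlation, 0.111 with quantile normalization, 0.0563 without feeder-free replicate 1). CLDN4, a tight junction claudin, rose from 302 ± 11.3 to 771 ± 44.3 FPKM. The list of neuroectoderm genes was not called (camera adjusted p = 0.819), and CDX2 was too low to be tested. Endothelial and blood genes were called upward, with 2 of 4 higher and none lower, as adjusted over the list alone (camera adjusted p = 0.0323). That call was lost with an estimated correlation (camera adjusted p = 0.171) and with quantile normalization (0.0748), among others.

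Targets of FGF and ERK signalling fell, with 10 of 14 members lower and 2 higher, the same counts adjusted over the list alone (camera adjusted p = 0.0272, adjusted p = 0.321 with an estimated correlation, 0.062 without feeder-free replicate 1). The feedback inhibitors SPRY1 and SPRY2 went from 17.5 ± 0.682 to 5.14 ± 0.791 FPKM and from 64.1 ± 3.76 to 25.4 ± 3.36 FPKM, and the ERK phosphatase gene DUSP5 from 119 ± 1.18 to 69.1 ± 3.90 FPKM. Among 12 tested BMP targets 5 rose and 1 fell, with the same counts adjusted over the list alone. GATA2 and GATA3, given above with the trophectoderm genes, belong to this list too. The list was not called with camera (camera adjusted p = 0.0802, adjusted p = 0.321 with an estimated correlation). Fry, which called most of the tested lists here, called it upward (fry adjusted p = 0.00121). With quantile normalization camera called it as well (camera adjusted p = 0.0199). Its median log2 fold change was -0.09 and its mean 0.50, which differ in sign, and the direction of camera was upward. ID1, a direct BMP target (chromosome 17, 40187156 to 40188384), went from 122 ± 8.91 to 245 ± 8.66 FPKM (log2 fold change 1.00, SE 0.08, limma adjusted p = 4.2e-05) and ID2 from 4.78 ± 1.03 to 15.1 ± 7.03 FPKM. The ligand gene BMP4 rose from 1.44 ± 0.259 to 4.44 ± 0.312 FPKM and the receptor gene BMPR2 fell from 6.93 ± 1.41 to 2.87 ± 0.15 FPKM, in a list of BMP ligands and receptors with 1 member higher and 6 of 10 lower, also as adjusted over the list alone (camera adjusted p = 0.453).

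Core pluripotency genes went both ways, with 3 of 13 higher and 5 lower, the same counts adjusted over the list alone (camera adjusted p = 0.813). LIN28B fell from 41.1 ± 4.01 to 11.7 ± 2.83 FPKM. NANOG went from 101 ± 3.84 to 119 ± 9.80 FPKM (log2 fold change 0.24, SE 0.08, limma adjusted p = 0.0229), a call that was lost with quantile normalization and without with-feeder replicate 2 or 3. DNMT3B, a DNA methyltransferase of primed cells, went from 1076 ± 16.6 to 868 ± 21.0 FPKM, a call lost with TMM factors. Of 12 genes of primed pluripotency 8 fell and 2 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.259), such as ZIC5 from 27.2 ± 0.381 to 9.14 ± 1.75 FPKM and SFRP2 from 45.4 ± 0.765 to 28.0 ± 0.54 FPKM. The endoderm regulator GATA6 rose from 0.719 ± 0.0648 to 7.49 ± 1.55 FPKM. Its endoderm list had 2 of 5 members higher and 2 lower, as adjusted over the list alone, and was not called (camera adjusted p = 0.493). In a list of fibroblast genes, which would also mark feeder cells, 4 of 12 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.121). The risers TAGLN (70.4 ± 6.36 to 543 ± 88.8 FPKM) and ACTA2 (5.66 ± 0.619 to 43.9 ± 5.43 FPKM) encode proteins of the contractile cytoskeleton. COL1A1 stood at 23.2 ± 12.7 FPKM with feeder cells and at 27.6 ± 18.1 FPKM without them (limma adjusted p = 0.761), in a row of 526 bp.

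**Figure D2:**
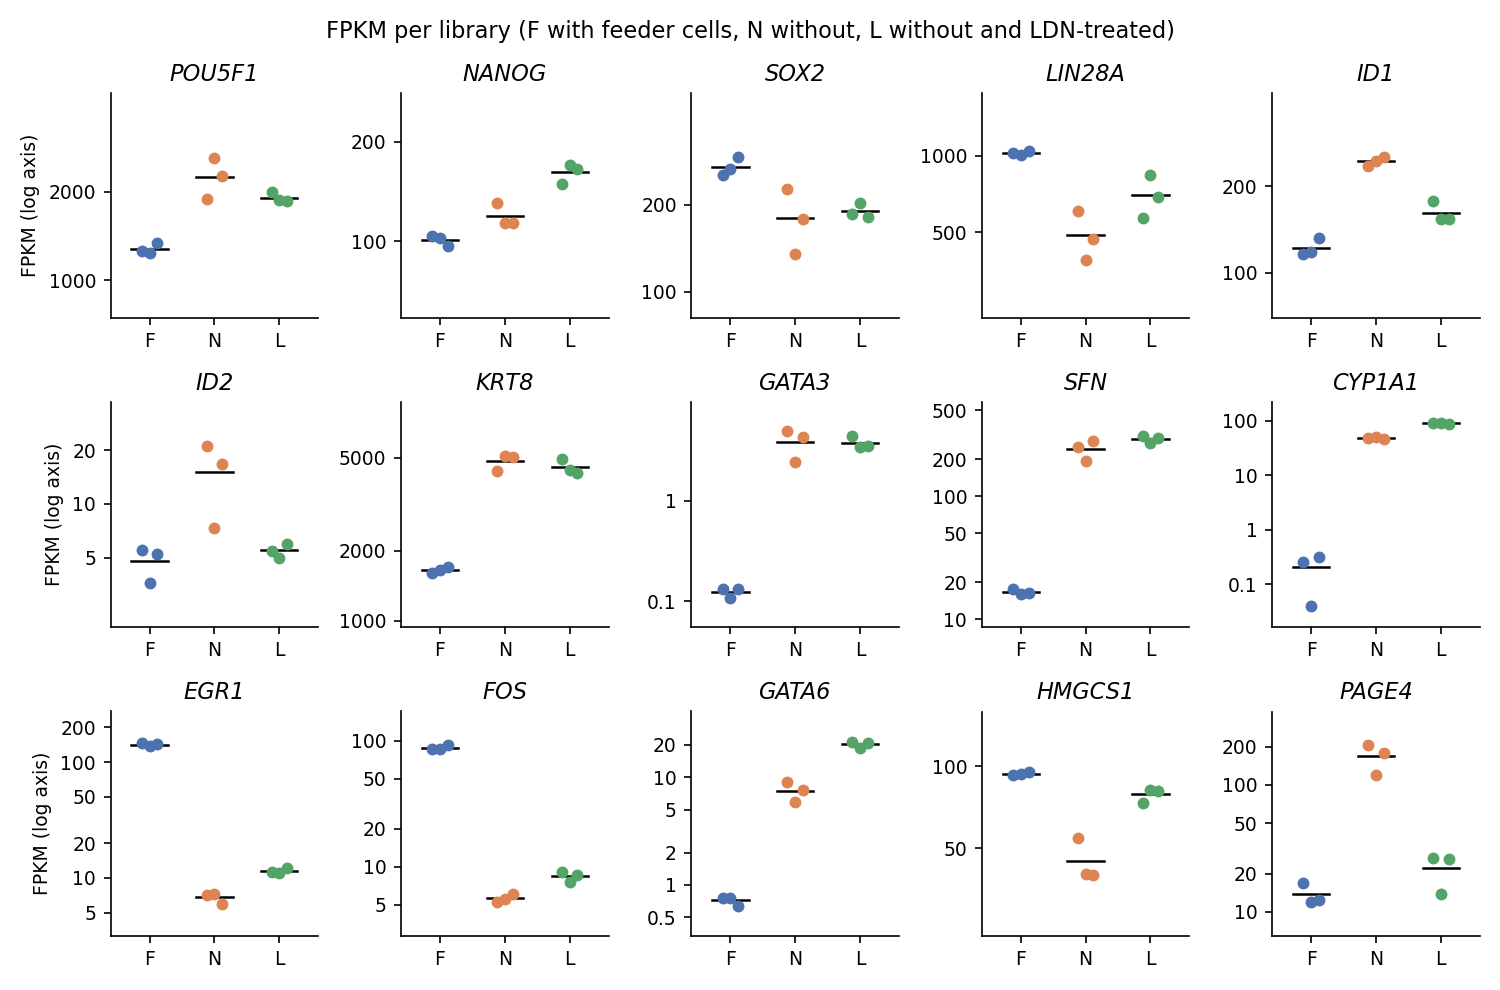
FPKM of 15 genes in each of the 9 libraries (log axis, points), with the group mean as a line, for cells with feeder cells (F), without feeder cells (N) and without feeder cells with LDN (L). KRT8, GATA3, SFN and CYP1A1 are higher and EGR1 and FOS lower in every feeder-free library than in any with-feeder library.

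In all, 2750 genes were higher and 5397 lower without feeder cells, 61.6% of those tested, and 67.5% of tested genes did not overlap between the groups, where chance gives 10% for 3 against 3. At a log2 fold change of at least 1, 314 were higher and 1591 lower. The surplus of lower genes was not seen with quantile normalization (4096 higher and 3853 lower) or with TMM factors (4413 and 3787). Both centre the fold changes (median log2 0.0282 and 0.0277), so these counts decide nothing about scaling between libraries. In the values as deposited, the median log2 fold change of all tested genes was -0.18. Lower calls were concentrated in genes with a long genomic span. In the longest of the 4 classes 2110 genes were lower and 258 higher, and in the shortest 691 were lower and 1113 higher.

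**Figure D3:**
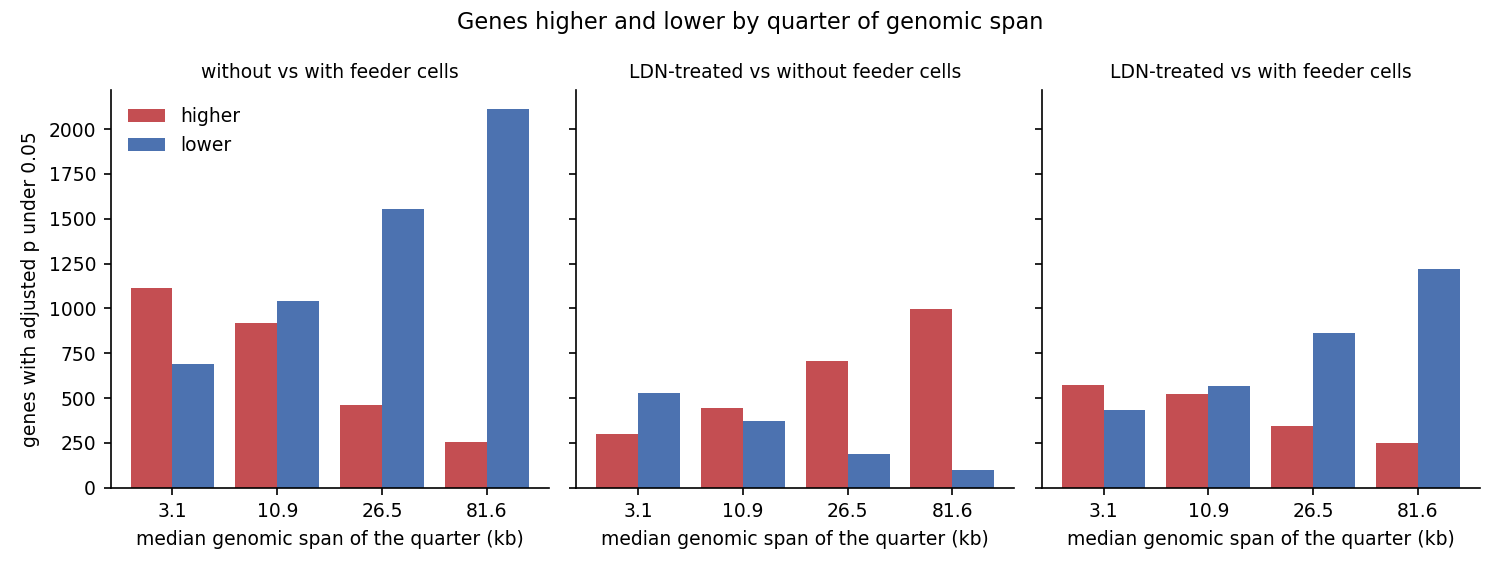
Number of genes higher (red) and lower (blue) at an adjusted p under 0.05 in each of 4 classes of genomic span of equal size, from the shortest to the longest, for the 3 comparisons. The longest class holds 2110 lower and 258 higher genes without against with feeder cells, and 99 lower and 999 higher genes with LDN against without feeder cells.

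The second comparison asked what the BMP receptor inhibitor changed in feeder-free cells. The BMP target ID1 fell from 245 ± 8.66 to 162 ± 14.0 FPKM (log2 fold change -0.60, SE 0.08, limma adjusted p = 0.0053) and ID2 from 15.1 ± 7.03 to 5.50 ± 0.504 FPKM (log2 fold change -1.20, SE 0.31, limma adjusted p = 0.0259). Of 14 genes of cholesterol synthesis 9 rose, and GATA6 rose further, from 7.49 ± 1.55 to 20.5 ± 1.40 FPKM (log2 fold change 1.35, SE 0.14, limma adjusted p = 0.00282). The endoderm list that holds GATA6 had 2 of 5 members higher and none lower (2 and 1 adjusted over the list alone), and was not called (camera adjusted p = 0.543). NANOG rose from 119 ± 9.80 to 162 ± 11 FPKM (limma adjusted p = 0.0103), a call lost without feeder-free replicate 3. POU5F1 (2249 ± 349 and 1910 ± 80.5 FPKM, limma adjusted p = 0.115) and SOX2 (180 ± 46.0 and 190 ± 10.8 FPKM, limma adjusted p = 0.645) were not called. Without feeder-free replicate 1, POU5F1 was called lower (log2 fold change -0.34, limma adjusted p = 0.00493).

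Of 12 BMP targets 3 fell and 1 rose (4 and 2 adjusted over the list alone), while 7 fell with quantile normalization and 6 with TMM factors, and none rose with either. The list was not called with camera (camera adjusted p = 0.064, adjusted p = 0.506 with an estimated correlation). Fry called it downward (fry adjusted p = 0.0373) and also called most other tested lists, up or down. Among these were the neuroectoderm and the endothelial and blood lists, both downward (fry adjusted p = 0.0441 and 0.012). With quantile normalization camera called the BMP target list downward too (camera adjusted p = 0.0092). SMAD6, an inhibitor of BMP signalling, went from 1.89 ± 0.197 to 1.10 ± 0.326 FPKM and BAMBI, a decoy receptor, from 9.27 ± 0.50 to 11.4 ± 0.295 FPKM. The call of SMAD6 was lost without any 1 of the 9 libraries, and that of BAMBI without any but feeder-free replicate 1 and with quantile normalization or TMM factors. That of ID2 was lost without feeder-free replicate 3 or any 1 of the LDN-treated replicates. GATA3 stood at 3.89 ± 1.30 FPKM without and 3.81 ± 0.526 FPKM with LDN (limma adjusted p = 0.976). Among BMP ligands and receptors 4 of 10 rose and none fell, as adjusted over the list alone (camera adjusted p = 0.109), with the type I receptor gene ACVR1 going from 8.09 ± 1.67 to 15.1 ± 0.485 FPKM and BMPR2 from 2.87 ± 0.15 to 6.73 ± 0.705 FPKM. The trophectoderm list had 1 member higher and none of 8 lower, as adjusted over the list alone (camera adjusted p = 0.417). That member, TFAP2C, rose from 14.0 ± 2.91 to 23.2 ± 1.39 FPKM, a call lost with only the 6 samples of the 2 groups (limma adjusted p = 0.051), and KRT8 stood at 4843 ± 397 and 4550 ± 342 FPKM (log2 fold change -0.09, limma adjusted p = 0.378). With quantile normalization 3 members were higher and 1 lower, and KRT8 was called higher (log2 fold change 0.22). With TMM factors 1 member was higher and 2 lower.

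In the cholesterol synthesis list 9 of 14 members rose and none fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00954, adjusted p = 0.194 with an estimated correlation, 0.155 without feeder-free replicate 1). CYP51A1, which encodes lanosterol demethylase, went from 31.7 ± 2.08 to 53.1 ± 0.869 FPKM, HMGCS1, which makes HMG-CoA, from 45.0 ± 8.37 to 78.8 ± 4.93 FPKM, and HMGCR, the rate-limiting reductase, from 41.1 ± 4.56 to 65.5 ± 4.31 FPKM. Targets of FGF and ERK signalling rose (7 of 14, none lower, as adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.506 with an estimated correlation, 0.0554 without feeder-free replicate 1, 0.0512 with TMM factors), for example EGR1 from 6.80 ± 0.728 to 11.5 ± 0.548 FPKM. SPRED1 rose from 2.62 ± 0.657 to 5.71 ± 1.36 FPKM, a call lost without LDN-treated replicate 2. Glycolysis genes fell (7 of 15 lower and 1 higher, 8 and 2 adjusted over the list alone, camera adjusted p = 0.008, adjusted p = 0.194 with an estimated correlation). That list's call was lost with quantile normalization (camera adjusted p = 0.418), with GAPDH at 6803 ± 765 and 4782 ± 232 FPKM. Core pluripotency genes had 4 of 13 members higher and none lower, as adjusted over the list alone (camera adjusted p = 0.973), including LIN28B (11.7 ± 2.83 to 20.2 ± 4.09 FPKM) and LIN28A (489 ± 112 to 698 ± 134 FPKM, limma adjusted p = 0.0477). The groups overlapped for LIN28A, and its call held only without feeder-free replicate 1 or LDN-treated replicate 1 among the fits that left out a library. That of LIN28B was lost without replicate 2 or 3 of either group. DNMT3B rose from 868 ± 21.0 to 1040 ± 67.4 FPKM, a call lost with TMM factors and without feeder-free replicate 3 or LDN-treated replicate 2 or 3. COL1A1 was not called (limma adjusted p = 0.504).

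The largest rises were in MTMR12, NFKB1, KITL, FGF2, PRRC1 and CLTC, with log2 fold changes from 2.25 (SE 0.43) for MTMR12 to 1.49 (SE 0.36) for CLTC. NFKB1, a subunit of the transcription factor NF-kappa-B, rose from 11.1 ± 1.00 to 47.2 ± 11.6 FPKM, KITL, a growth factor of germ and blood cells, from 1.52 ± 0.76 to 7.27 ± 0.0932 FPKM, and FGF2, which was also in the medium as a protein, from 10.5 ± 4.41 to 31.7 ± 6.85 FPKM. The gene with the largest fall was PAGE4, a cancer/testis antigen gene of the X chromosome, from 168 ± 43.6 to 22.1 ± 7.28 FPKM (log2 fold change -2.90, SE 0.27, limma adjusted p = 0.00259), against 13.7 ± 2.74 FPKM with feeder cells. PTH2, PBD-2, FXYD4 and FOLR1, a folate receptor gene, and 1 of 3 tested rows of the small nucleolar RNA U3 also fell, with log2 fold changes of -2.04 (SE 0.49), -2.02 (SE 0.50), -1.75 (SE 0.51), -1.47 (SE 0.18) and -1.87 (SE 0.56). Leaving out 1 library ended the call of U3 for each of the 6 libraries of these groups, that of FXYD4 for each but feeder-free replicate 2 and for with-feeder replicate 3, that of PBD-2 for feeder-free replicate 3 and LDN-treated replicates 1 and 3, and that of PTH2 for feeder-free replicates 2 and 3 and LDN-treated replicate 2. It ended the calls of FGF2 and PRRC1 for feeder-free replicate 3 and LDN-treated replicate 2, that of MTMR12 for the latter, and that of CLTC for replicates 2 and 3 of both groups.

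With LDN 2450 genes were higher and 1193 lower, and 40.7% of tested genes did not overlap between the groups, where chance gives 10%. At a log2 fold change of at least 1 the numbers were 183 and 34. With quantile normalization 1693 were higher and 1667 lower, and with TMM factors 1818 and 1875. The counts rested on single libraries, with 280 higher and 154 lower without feeder-free replicate 3, 316 and 209 without LDN-treated replicate 2, 470 and 260 without LDN-treated replicate 3, 917 and 560 without feeder-free replicate 2, and 4120 and 1951 without feeder-free replicate 1. With only the 6 libraries of the 2 groups in the fit they were 296 and 205. The main fit shares its spread with the with-feeder libraries, which lay closer together, so its p-values here may be too small. Long genes led the rise, with 999 higher and 99 lower in the longest class of genomic span and 298 and 531 in the shortest.

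**Figure D4:**
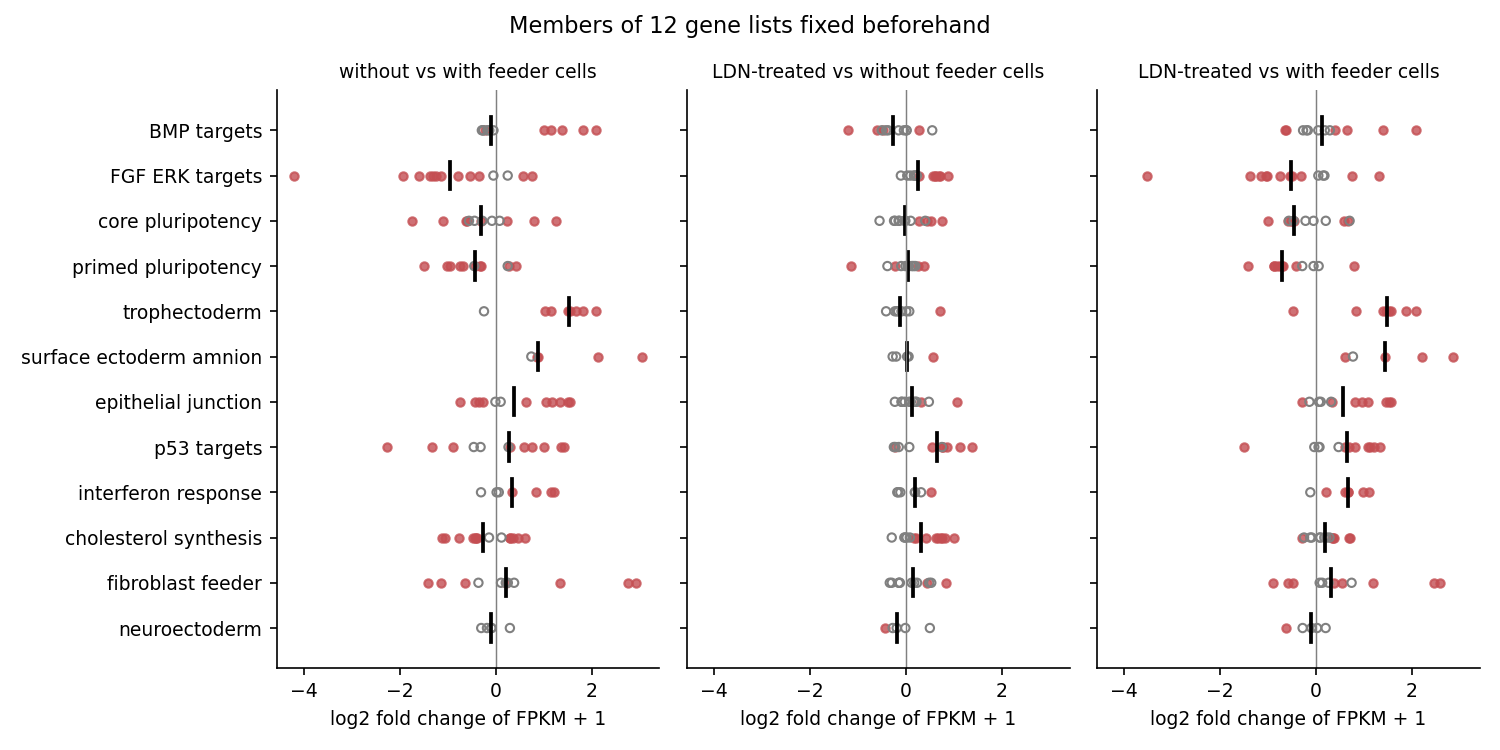
Log2 fold change of each tested member of 12 gene lists in the 3 comparisons, with members at an adjusted p under 0.05 in red, others as open circles and the list median as a black bar. Of the 8 trophectoderm members 7 lie to the right in both comparisons against with-feeder cells (medians 1.53 and 1.49 over all 8), and the list lies near 0 with LDN against without feeder cells (median -0.12).

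The third comparison set the LDN-treated feeder-free cells against cells with feeder cells, the pair named in the study's design. CYP1A1 rose from 0.206 ± 0.148 to 90.1 ± 1.53 FPKM (log2 fold change 6.25, SE 0.10, limma adjusted p = 1.72e-09). SFN, TACSTD2, UPK2 and VGLL1 rose as well, the epithelial surface protein gene TACSTD2 from 8.92 ± 2.06 to 196 ± 19.4 FPKM and VGLL1, a cofactor of TEAD transcription factors, from 3.31 ± 0.731 to 60.2 ± 4.34 FPKM. FXYD4 also rose (log2 fold change 3.71, SE 0.51). EGR1 and FOS were lower, at 11.5 ± 0.548 and 8.40 ± 0.795 FPKM, and the tachykinin gene TAC3 fell from 149 ± 7.03 to 26.0 ± 2.58 FPKM (log2 fold change -2.47, SE 0.10). CDH2, the N-cadherin gene, fell from 79.5 ± 17.5 to 18.0 ± 5.77 FPKM. A row of U3 and the ribosomal RNA row 5_8S_rRNA were also lower (log2 fold changes -2.56, SE 0.58, and -2.28, SE 0.56), the latter not without LDN-treated replicate 1. Ribosomal RNA is a remnant in poly-A libraries.

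Trophectoderm genes were higher in 7 of 8 members and lower in 1, as adjusted over the list alone (camera adjusted p = 2.24e-06), and epithelial junction genes were higher in 7 of 12 and lower in 1, as adjusted over the list alone (camera adjusted p = 2.74e-05). Both lists were called with an estimated correlation too (adjusted p = 0.0376). So were targets of p53 (7 of 12 higher, 1 lower, and 8 and 1 adjusted over the list alone, camera adjusted p = 7.16e-05), genes of endoplasmic reticulum and amino acid stress (7 of 14 higher, none lower, as adjusted over the list alone, camera adjusted p = 6.87e-06) and interferon response genes (6 of 7 higher, none lower, as adjusted over the list alone, camera adjusted p = 0.000298). Examples are KRT19 (405.5 ± 9.49 to 1161 ± 89.9 FPKM), OCLN (27.7 ± 0.626 to 54.9 ± 3.00 FPKM), and the p53 targets PHLDA3 (334 ± 19.2 to 772 ± 60.9 FPKM) and FAS (4.81 ± 0.238 to 13.7 ± 1.32 FPKM). Others are the stress genes ATF3 (22.5 ± 2.15 to 55.9 ± 0.82 FPKM) and PHGDH (124 ± 5.53 to 283 ± 19.1 FPKM), and ISG15 (7.59 ± 1.09 to 17.4 ± 2.15 FPKM), a ubiquitin-like protein gene induced by interferon. Surface ectoderm and amnion genes were higher in 4 of 5 (5 adjusted over the list alone, camera adjusted p = 0.000135, adjusted p = 0.205 with an estimated correlation), with IGFBP3 going from 17.9 ± 0.794 to 50.3 ± 1.26 FPKM.

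Genes of primed pluripotency fell (8 of 12, 1 higher, as adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.428 with an estimated correlation), ZIC5 from 27.2 ± 0.381 to 9.58 ± 1.52 FPKM and SFRP2 from 45.4 ± 0.765 to 27.9 ± 1.54 FPKM. CD24, a surface marker in the same list, rose from 909.6 ± 26.6 to 1575 ± 32.9 FPKM. Targets of FGF and ERK signalling fell as well (9 of 14, 2 higher, as adjusted over the list alone, camera adjusted p = 0.0294, adjusted p = 0.328 with an estimated correlation, 0.069 without feeder-free replicate 1, 0.0888 with only the 6 samples of the 2 groups), for example DUSP6 from 115 ± 5.82 to 56.5 ± 4.47 FPKM. Core pluripotency genes had 2 of 13 members higher and 5 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.809). POU5F1 and NANOG were higher (1281 ± 53.1 to 1910 ± 80.5 FPKM and 101 ± 3.84 to 162 ± 11 FPKM), and SOX2 and LIN28A were lower (270 ± 19.1 to 190 ± 10.8 FPKM and 1026 ± 21.3 to 698 ± 134 FPKM). The calls of SOX2 and LIN28A were lost without any 1 of the with-feeder replicates or without LDN-treated replicate 1 or 3, and that of SOX2 with TMM factors. DNMT3B did not pass (1076 ± 16.6 and 1040 ± 67.4 FPKM, limma adjusted p = 0.493), though it did with quantile normalization. ID1 remained above its with-feeder level (162 ± 14.0 against 122 ± 8.91 FPKM, limma adjusted p = 0.0048), and for ID2 no difference was called (5.50 ± 0.504 against 4.78 ± 1.03 FPKM, limma adjusted p = 0.67). The BMP target list had 4 of 12 members higher and 2 lower, as adjusted over the list alone. It was not called with camera (camera adjusted p = 0.166, adjusted p = 0.428 with an estimated correlation). With fry, which called most of the tested lists here too, it was called upward (fry adjusted p = 0.0261). GATA6 was 20.5 ± 1.40 FPKM against 0.719 ± 0.0648 FPKM (log2 fold change 3.64, SE 0.14). Its endoderm list had 1 of 5 members higher and 2 lower, as adjusted over the list alone, and was not called (camera adjusted p = 0.326). COL1A1 was not called (limma adjusted p = 0.336).

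Compared with feeder cells, 1691 genes were higher and 3087 lower with LDN, 286 and 338 of them at a log2 fold change of at least 1, and 59.4% of tested genes did not overlap, where chance gives 10%. With quantile normalization 2356 were higher and 2467 lower, and with TMM factors 2514 and 2071. The lower count fell to between 1772 and 1946 without LDN-treated replicate 1 (1772), LDN-treated replicate 3 (1906) or with-feeder replicates 1 (1946), 2 (1820) or 3 (1902). In the longest class of genomic span 248 genes were higher and 1221 lower, and in the shortest 576 and 434. Here too, the labels give the SSEA4 sort for the with-feeder cells only.

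Both feeder-free groups were compared with the same with-feeder libraries, and 4024 genes were called in the same direction in both, 1337 higher and 2687 lower, against 31 called in opposite directions. Independent lists of these lengths would share 352 and 1260 genes, and simulated unchanged groups, in which hardly any gene is called, shared on average 0.04 genes, so that count does not weigh the shared libraries. Fold changes of the 2 comparisons correlated at 0.824 across genes, which are not independent replicates, where simulated unchanged groups gave 0.499, and their covariance was 0.296 against 0.0178. The 3 control libraries were not divided, since a part would hold fewer than 2 libraries, and part of the excess may come from them. Without LDN-treated replicate 1 the overlap was 2450, and without with-feeder replicate 1, 2 or 3 it was 2633, 2507 or 2681. In the other direction, 2880 genes that changed without feeder cells were called the opposite way with LDN, 805 of them higher and 2075 lower without feeder cells, and 179 were called the same way both times. Independent lists would give 248 and 1000 genes, and simulated unchanged groups gave none, which again does not weigh the shared libraries. The correlation of these fold changes was -0.686 (simulated -0.50) and the covariance -0.192 (simulated -0.0179), and both comparisons share the 3 untreated feeder-free libraries, which were not divided either. This count was 290 without feeder-free replicate 3, 363 without LDN-treated replicate 2, 553 without LDN-treated replicate 3, 1055 without feeder-free replicate 2, 5144 without feeder-free replicate 1, and 1868 or 1851 without with-feeder replicate 1 or 2. The simulations drew the spread independently for each gene and library, so they hold no gradient between libraries. With LDN against without feeder cells, the longest span class lay above the shortest by a median log2 fold change of 0.287 at a matched level. How far a gradient between libraries makes up the reversals was not tested.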

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

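Cyclic loess normalization, leaving out small RNA rows and removing the genomic span trend were chosen after the data had been seen. Of 117 named gene results, 109 were called, 73 of these under all 20 alternatives run on genes. Another 10 were called under each that tested them, since a filter left them out of at least 1. In all, 26 were lost under at least 1, and none of the called changed direction. Most of these genes were named because they were called, so these numbers do not measure how stable calls are in general. Of all 3643 calls with LDN against without feeder cells, 495 were shared with the fit to only the 6 samples of the 2 groups. KRT8, not called with LDN against without feeder cells, turned to a log2 fold change of 0.22 with quantile normalization. Scaling moved the counts of genes beyond 1.5 times only for genes higher without against with feeder cells (4413 with TMM factors), for genes lower with LDN against without feeder cells (1875 with TMM factors) and for genes higher in that comparison (1608 with the genomic span trend removed). The cause was not tested. A minimum log2 fold change of 1 left 314 and 1591 genes without against with feeder cells, 183 and 34 with LDN against without, and 286 and 338 with LDN against with feeder cells, as a stricter threshold must. The LDN against without comparison was the least stable. With only the 6 samples of the 2 groups it called 296 higher and 205 lower genes and 351 reversals, and 16 calls of named genes ended (MTMR12, CLTC, PTH2, PBD-2, U3, FXYD4, SMAD6, BAMBI, SPRED1, LIN28A, LIN28B, TFAP2C, ID2, DNMT3B, DLK1 and DPPA5). The same fit raised the calls of LDN against with feeder cells to 2139 higher and 4204 lower, and the overlap to 5033. Fold changes are the same in both fits, so only the estimated spread differed. The main fit takes the same spread for all groups, while the untreated feeder-free libraries lay furthest apart (correlations 0.974 to 0.985). Its p-values may therefore be too small for LDN against without feeder cells and too large for LDN against with feeder cells. For LDN against without feeder cells, leaving out 1 library gave 280 to 4120 higher and 154 to 1951 lower genes, and 290 to 5144 reversals. The lowest came without feeder-free replicate 3 and the highest without feeder-free replicate 1. For LDN against with feeder cells, leaving out 1 library gave 1772 to 4000 lower genes, and an overlap of 2450 to 5061. The cause was not tested.

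Replicate numbers did not pair the libraries. Same-numbered deviations correlated between -0.303 and 0.0303, and the best match had the same number in 5 of 18 cases. With the replicate block (fewer residual degrees of freedom), LDN against without feeder cells had 568 higher and 324 lower genes, reversals numbered 653, and the BMP target list was called (adjusted p = 0.0362). The other counts of genes with the block stayed within 1.5 times. It ended 11 calls of named genes, at limma adjusted p from 0.0503 to 0.0957: NANOG without against with feeder cells, CLTC, PBD-2, FXYD4, SMAD6, BAMBI, LIN28A, LIN28B and DNMT3B with LDN against without, and SOX2 and LIN28A with LDN against with feeder cells.

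The number of lists called without against with feeder cells was 10, and it fell to 6 with no filter on low values, 5 with quantile normalization, 5 with cyclic loess and 0 with an estimated correlation. Leaving out 1 library gave 3 to 10, the lowest without feeder-free replicate 1, where the calls of the FGF and ERK, germ cell, endothelial and blood, epithelial junction, glycolysis, endoplasmic reticulum stress and interferon lists were lost. For LDN against without feeder cells 5 lists were called, 0 with an estimated correlation, and 3 to 6 with 1 library left out, again lowest without feeder-free replicate 1, where those of the FGF and ERK and the cholesterol lists were lost. For LDN against with feeder cells 13 were called, and 5 with an estimated correlation. Those of the FGF and ERK and the primitive streak lists were lost without feeder-free replicate 1. The BMP target list was called without against with feeder cells with quantile normalization (0.0199) and cyclic loess (0.0217), and with LDN against without feeder cells with quantile normalization (0.0092) and cyclic loess (0.0207). Its adjusted p there ranged from 0.0177 to 0.182 over the fits without 1 library, and lay under 0.05 without with-feeder replicate 2, feeder-free replicate 2 or LDN-treated replicate 1. The direction of camera turned, with no call, under quantile normalization and cyclic loess for glycolysis (adjusted p = 0.925 and 0.909) and ribosomal proteins (0.495 and 0.767) without against with feeder cells, oxidative phosphorylation with LDN against without (0.988 and 0.997), and ribosomal proteins with LDN against with feeder cells (0.247 and 0.194). The depth per library was estimated only relative to the others (0.868 to 1.247), so what it limits was not measured. In simulated data, with no gradient between libraries and 200 changed genes, genes changed 1.5-fold were recovered in 45.5% of cases. That share need not hold for the data.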

Other observations

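The tests of the gradient between libraries, of genomic span and of the splits of the libraries were written down before their results were seen, and the tests of scaling, of the sort, of FGF and ERK signalling and of admixed cells were chosen after the result was seen. Several lists not described above also moved. Without against with feeder cells, the germ cell list had 4 of 5 members higher and 1 lower (camera adjusted p = 0.0272, adjusted p = 0.171 with an estimated correlation), with SOX15 going from 46.0 ± 4.03 to 159 ± 15.5 FPKM (SD, n = 3 libraries here and below). That call was lost under several alternatives, among them quantile normalization (camera adjusted p = 0.0748), TMM factors (0.0955) and leaving out feeder-free replicate 1 (0.0563). Interferon response genes were higher in 4 of 7 (camera adjusted p = 0.0272, adjusted p = 0.171 with an estimated correlation), for example IRF1 from 4.16 ± 0.259 to 8.19 ± 0.68 FPKM. This call was lost with no filter on low values, with TMM factors and without feeder-free replicate 1 (camera adjusted p = 0.0605, 0.0503 and 0.0563). The counts of both lists were equal when adjusted over the list alone. Ribosomal protein genes rose without against with feeder cells (12 of 16, none lower, as adjusted over the list alone, camera adjusted p = 5.92e-06, adjusted p = 0.321 with an estimated correlation). They fell with LDN against without feeder cells (12 of 16, and 13 adjusted over the list alone, none higher, camera adjusted p = 1.14e-06, adjusted p = 0.506 with an estimated correlation). Both calls were lost with quantile normalization (camera adjusted p = 0.495 and 0.993), the first with its direction turned, and the members then went both ways (4 higher and 7 lower, and 1 and 1).

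With LDN against with feeder cells, the fibroblast list was called upward (5 of 12 higher, 3 lower, as adjusted over the list alone, camera adjusted p = 0.0213, adjusted p = 0.217 with an estimated correlation). Its members TAGLN and ACTA2 stood at 427 ± 21.5 and 35.5 ± 2.83 FPKM with LDN, against 70.4 ± 6.36 and 5.66 ± 0.619 FPKM with feeder cells. The germ cell list had 4 of 5 members higher and 1 lower in this comparison, as adjusted over the list alone (camera adjusted p = 0.00262). Among the alternatives, its call was lost only with an estimated correlation (camera adjusted p = 0.066). Genes of the primitive streak and mesoderm were higher in 3 of 5 (4 adjusted over the list alone, camera adjusted p = 0.0363, adjusted p = 0.186 with an estimated correlation), such as GSC from 0.818 ± 0.515 to 3.08 ± 0.559 FPKM. The call of this list was lost with quantile normalization, with TMM factors and without feeder-free replicate 1 (camera adjusted p = 0.0778, 0.105 and 0.0621), as well as with the span trend removed (0.116) and with only the 6 samples of the 2 groups (0.0535), and that of the fibroblast list with TMM factors (0.0563). Imprinted genes moved both ways without against with feeder cells (3 of 9 higher, 4 lower, as adjusted over the list alone, camera adjusted p = 0.493). DLK1, an imprinted growth regulator, stood at 0.597 ± 0.257 FPKM with feeder cells, 2.10 ± 0.595 without and 0.553 ± 0.35 with LDN. DPPA5, a gene of naive pluripotency, stood at 6.19 ± 2.53, 25.4 ± 11.2 and 8.06 ± 0.715 FPKM. Its list had 2 of 5 members higher and none lower without against with feeder cells, as adjusted over the list alone (camera adjusted p = 0.347). In LDN against without feeder cells 1 was higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.838). With LDN against without feeder cells the calls of DLK1 and DPPA5 were lost without feeder-free replicate 3 or LDN-treated replicate 2, and that of DPPA5 also without LDN-treated replicate 3.

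More genes were lower than higher without feeder cells, and the excess was concentrated in genes with a long genomic span. Fold changes also varied with level over 10 bins of mean level. Their median log2 was -0.395 in the bin around 3.18 FPKM and 0.183 in the highest bin, around 173 FPKM. With LDN against without feeder cells these medians were 0.187 and -0.0912. The cause of this trend was not tested. Without against with feeder cells, 48.5% of calls were lower with quantile normalization, against 66.2% as deposited. That normalization itself centres the fold changes (median log2 0.0282), so this share decides nothing about scaling between libraries, which stays open for the imbalance. At a matched level, the longest of 4 span classes had a median log2 fold change lower than the shortest (-0.555, SE 0.0322 over 10 bins, negative in all 10, and -0.532 with quantile normalization). A loss of signal from genes with a long genomic span predicts this. The span is the distance between a gene's start and end in the genome, and transcript length could not be checked, so a loss from long transcripts was not tested. A gradient between libraries may also be at work: across genes, which are not independent replicates, the difference of feeder-free replicates 2 and 1 correlated with that of replicate 3 and the with-feeder mean (r = 0.451, and 0.411 with the span trend removed), although of the other arrangements 1 gave 0.457 and 1 gave -0.0782. RNA quality per library is not given in the sources used here, so a technical gradient and a change of long genes in the cells, untested, both stay open.

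EGR1, FOS, EGR2 and JUNB were lower in both feeder-free groups, EGR2 at 6.75 ± 0.104 FPKM with feeder cells and 0.628 ± 0.318 without them, and JUNB at 20.0 ± 2.24 and 10.4 ± 1.70 FPKM. Handling during the sort may have raised them in the with-feeder cells, and of the 5 other tested immediate early genes 2 were lower (DUSP1 and NR4A1) and 2 higher (JUN and ATF3) with LDN against with feeder cells. The labels give the sort for the with-feeder cells only, so that the sort and the group cannot be told apart. Lower FGF and ERK signalling in the feeder-free cells is another candidate explanation, as the list of its targets without EGR1 lay below all tested genes by a median log2 fold change of -0.852 after cyclic loess (-0.389 with LDN against with feeder cells), with 8 of 13 members lower in each comparison. Both stay open, and JUNB, DUSP1, NR4A1 and JUN were named after their values were seen.

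The higher trophectoderm and surface ectoderm genes in both feeder-free groups may come from differentiated cells, if the SSEA4 sort took these out of the with-feeder samples only. Cells of many lineages would have raised the markers of other lineages too, and the mean log2 fold change was 1.32 for 8 trophectoderm genes, against 0.68 for 4 endothelial and blood genes (difference 0.637, SE 0.341), 0.20 for 5 endoderm genes (1.12, SE 0.693), 0.27 for 5 streak and mesoderm genes (1.05, SE 0.344) and -0.07 for 5 neuroectoderm genes (1.39, SE 0.272). The first pair of differences lies within 2 SE and the last pair beyond. These SEs come from the spread over the genes of a list, which are not replicates. The streak and mesoderm genes had with-feeder means of 0 to 1.16 FPKM, where the scale understates a change. The differences therefore cannot decide on a mixture of several lineages, which stays open. None of the 5 neuroectoderm genes, with means of 0.57 to 182 FPKM with feeder cells, was called. Of the 4 endothelial and blood genes, 2 were called higher and none lower. Trophectoderm-like cells stay open too, because CDX2 reached only 0.277 FPKM in any library, too low to decide, and the sort and the group cannot be told apart here either. A rise of these genes in the stem cells themselves was not tested.

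With 3 libraries against 3 there are 10 splits of the 6, too few for a share under 0.05. The real split called 8147 genes without against with feeder cells and the highest other split 1. With LDN against without feeder cells the numbers were 3643 and 2, and with LDN against with feeder cells 4778 and 1. Each other split mixes libraries of both groups, so a difference between the groups enters the spread and few calls can remain. The gap between these numbers therefore does not measure chance.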
